A study of Caenorhabditis elegans with 2 samples.

How the data were processed

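The series measured where the tagged transcription factor SPR-3 binds the genome of Caenorhabditis elegans. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole worms of strain OP703, which lack a working copy of unc-119 and carry a transgene that holds spr-3 joined to TY1, EGFP and FLAG tags together with a rescuing copy of unc-119. Per the labels, mixed-sex L4 larvae were collected at 49 hours after synchronisation by starvation at the L1 stage, chromatin was sheared by sonication, and an anti-GFP antibody pulled down the fusion protein. The labels name 2 biological replicates of 1 group, and no second condition, so no comparison between groups was possible. The comparisons made were replicate against replicate, peaks against random positions, peaks against gene annotation, and summit sequence against flanking sequence.

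The authors deposited 4 lists of intervals on the ce11 assembly. There were 30000 candidate intervals for replicate 1, 30000 for replicate 2 and 30000 for both replicates pooled, described in the deposit as peaks and background meant as input for an irreproducible discovery rate (IDR) analysis. The fourth list was the optimal IDR-thresholded set of 945 summits in 943 distinct intervals. Per the notes in the deposit, the same control file served for both replicates and for the pool, and the thresholded set was made from all 3 candidate lists. The aligner, the peak caller, their versions and the IDR cutoff are not given in the sources used here. All 945 thresholded intervals were found unchanged in the pooled candidates and were the 945 candidates of highest pooled signal, so a comparison with the highest pooled candidates was the same set and carried no information of its own.

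The signal of an interval is the value that the authors' peak caller gave it, for ChIP against control. Its scaling to sequencing depth is not given in the sources used here, so signal levels were not compared between lists. Signal was used to describe, rank and filter intervals, to compare classes of peaks within the pooled list by permutation of the median difference, and to correlate the replicates over matched peaks, which does not depend on a scaling factor per list. The authors also deposited a −log10 q-value per interval, which was only described. Per the deposited narrowPeak format, the last column is the summit offset in bp from the start of the interval, and 1 interval of replicate 2 had an offset outside its interval. The files hold no read counts, so the depth of each library is unknown and no interval that needs it was computed. Confidence intervals of shares are exact 95% binomial (Clopper-Pearson) intervals over peaks or genes, which cover counting error among peaks or genes and not variation between worms. The interval given for an odds ratio is a large-sample 95% interval on the log scale, with the same limit.

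Chromosome names and lengths were compared with the reference used here, assembly WBcel235 with the Ensembl release 115 gene annotation, and all intervals lay within its 6 nuclear chromosomes. Whether the authors used the same gene annotation is not given in the sources used here. Coordinates are 1-based on ce11. Of 19973 protein-coding genes, each was given a promoter window from 1000 bp upstream to 200 bp downstream of its annotated 5′ end. A summit was classed as promoter, exon, intron or intergenic in that order, and a summit in overlapping windows counted for every gene concerned.

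Replicate overlap was the share of the 945 peaks overlapped by at least 1 bp by the 945 highest-signal candidates of a replicate. It was set against 1000 random placements of the peaks within their chromosomes with a one-sided permutation test. Signal in the replicates was compared with Spearman's rho over peaks, using the candidate with the largest overlap. Its permutation p is not given, because the same control served both replicates and permuted signals do not share it. Values per replicate of single peaks come from the overlapping candidate with the nearest summit. Location classes and noncoding gene classes (summit within 200 bp of the gene) were set against 1000 random placements with two-sided permutation tests. Chromosomes and the central 50% of autosome length were tested against their share of the genome with two-sided exact binomial tests, and medians of signal with two-sided permutation tests of 100000 resamples. Peaks and genes are not independent replicates, so p-values describe these lists and not the spread between worm cultures. Benjamini-Hochberg adjustment was made within each family of tests, with a threshold of 0.05.

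The 19 gene lists were compared with all other protein-coding genes by two-sided Fisher exact tests of the share with a summit in the promoter window. They comprised presenilin and spr genes; CoREST, H3K4 demethylase and histone deacetylase genes; DREAM and synMuv B genes; pan-neuronal, neurotransmitter, neuropeptide, homeobox, nuclear hormone receptor, muscle, germline, sperm, intestine, cuticle collagen, ribosomal protein, histone, translation, mitochondrial respiratory chain, heat shock and stress, and cell cycle genes. The CoREST list also held histone methyltransferase genes and genes of their complexes. Of the listed symbols, opt-2 and daf-21 had no match in the annotation. Every 8-mer, read on either strand, was counted in windows of 75 bp on each side of a summit and in flank windows of the same size centred 500 bp away, and tested with one-sided Fisher exact tests. The numbers of peaks within 25 kb of spr-3 and unc-119 were set against 1000 random windows of 50 kb with one-sided permutation tests.

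The genes named were fixed by rule: the nearest gene, by its 5′ end, to each of the 25 peaks of highest signal; all presenilin and spr genes; spr-3 and unc-119; up to 4 members per gene list and up to 2 per noncoding class with the highest-signal peaks. The tests, lists, naming rule and the other settings listed next were chosen before the data were examined. These settings were the 472 peaks of highest signal, the 945 highest candidates of either replicate alone, an overlap of 50% of both intervals, 1890 candidates per replicate, a promoter window of 500 bp on each side, assignment of each peak to the nearest gene at any distance, exclusion of 5766 operon-like genes (5′ end within 1000 bp downstream of another gene on the same strand), a distance of 500 bp to noncoding genes, 6-mers, promoters without a peak as sequence background, peaks outside promoters, and 10 kb around the transgene loci. Settings added after the data were seen left out peaks near tRNA, snRNA and snoRNA genes or within 25 kb of spr-3, drew random summits from the other pooled candidates, or matched candidates by nearest summit.

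The procedures were tested on simulated data. In 20 sets of random peaks, 0 of 380 gene list tests, 1 of 80 location tests and 0 of 120 noncoding class tests passed the threshold. These peaks were placed uniformly within chromosomes, as in the location and noncoding tests themselves. They therefore do not show the rate of false calls for peaks concentrated in promoters. With 8, 17 or 25 peaks placed at ribosomal protein promoters among random peaks, the list was called each time. A word planted in 60 windows was recovered in 60 and led the list. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. Read alignments, signal tracks, the control and other SPR-3 or untagged ChIP-seq experiments were not used here.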

Results

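SPR-3 is a C2H2 zinc finger protein whose loss suppresses the egg-laying defect of worms mutant for the presenilin gene sel-12. Its binding was mapped by ChIP-seq in whole L4 larvae that carried a GFP-tagged transgene, in 2 biological replicates of 1 group. The thresholded set held 945 peaks with a median width of 430 bp (108 to 823 bp), which together covered 0.375 Mb or 0.374% of the genome. Their pooled signal, the authors' value for ChIP against control, had a median of 183.7 (interquartile range 155.1 to 241.0) and ran from 138.0 to 2033. The −log10 q-values of these peaks lay between 1.69 and 3.1. The pooled candidate list of 30000 intervals covered 12.1% of the genome with a median signal of 59.9, and the candidate lists of replicates 1 and 2 covered 12.3% and 12.1%.

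The replicate comparison asked how far the sites were shared by both libraries. The strongest sites were shared: each of the 25 peaks of highest pooled signal ranked within the top 40 candidates of both replicates. The peak at zip-11, which encodes a bZIP transcription factor, was the highest of each replicate, with signals of 1100 and 940.4, and the peak upstream of rpl-3, a gene for a large-subunit ribosomal protein, was the next in both (595.5 and 626.1). Over all 945 peaks, 747 (79.0%, exact 95% interval 76.3 to 81.6%) were overlapped by the 945 highest candidates of replicate 1 and 748 (79.2%, 76.4 to 81.7%) by those of replicate 2. Random placement gave 0.772% ± 0.289 (SD over 1000 placements) and 0.773% ± 0.298, and the one-sided permutation p was 0.001 for each, the smallest that the placements can give. Both replicates covered 595 peaks (63.0%), and 45 (4.76%) were covered by neither. Compared directly, 599 of the 945 highest candidates of replicate 1 (63.4%, 60.2 to 66.5%) were overlapped by those of replicate 2. Signal in the replicates was correlated across the 942 peaks matched in both (Spearman's rho = 0.482, Pearson's r of log2 signal 0.64). These peaks had been selected on the pooled signal of both libraries, and both signals were taken against the same control, so the overlap and the correlation describe a selected set and include what the control shares between replicates.

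**Figure D1:**
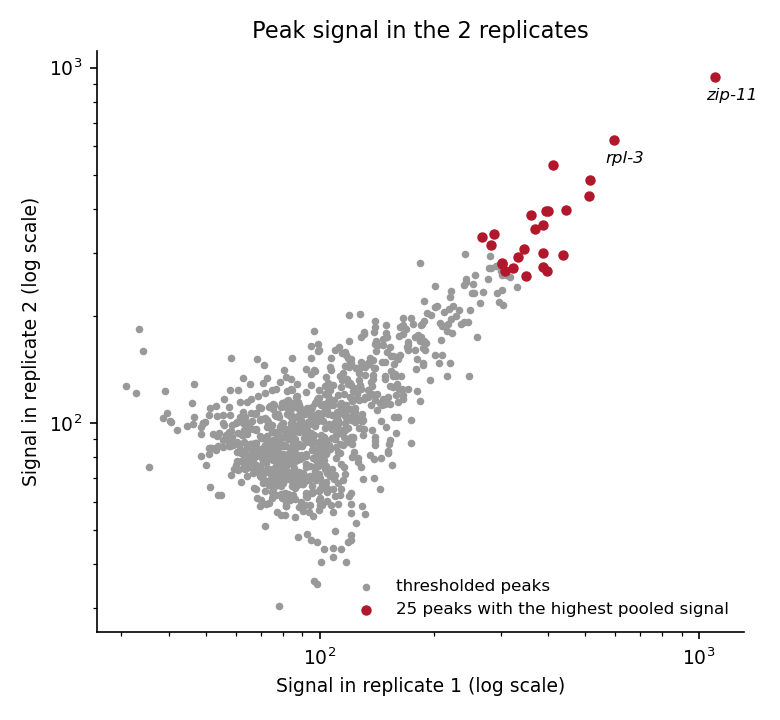
Signal of each thresholded peak in replicate 1 (x axis, log scale) against replicate 2 (y axis, log scale), as the authors' peak caller gave it, with the 25 peaks of highest pooled signal in red. The red points rank within the top 40 of both replicates, and zip-11 stands highest at 1100 and 940.4.

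The strongest sites lay mostly in promoters, and on X mostly outside them. Of the 25 highest peaks, 14 lay in a promoter window, 6 in introns and 5 between genes. The highest, at chromosome IV 3311223 to 3311671, had its summit 160 bp downstream of the 5′ end of zip-11 (signal 2033). It was followed by peaks 283 bp upstream of rpl-3 (III 3867380 to 3867744, signal 1220), between Y17G9B.5 and rpl-20 (IV 4749924 to 4750246, signal 1002), at F44E7.5 (V 5780755 to 5781085, signal 952.0) and upstream of tasp-1, which encodes a taspase-like threonine protease (III 10759099 to 10759413, signal 938.9). Other promoter peaks among the 25 stood at rpl-15 (846.0), the cytochrome c oxidase gene cox-5A (805.2), egg-5 (718.3), Y55F3AR.2 and the chaperonin gene cct-8 (696.6), nspc-17 (662.7), Y22D7AL.10 and the mitochondrial chaperonin gene hsp-60 (658.1), the AAA ATPase gene cdc-48.1 (605.4), the histone acetyltransferase gene cbp-1 (601.9) and the Integrator subunit gene ints-4 (580.7). The tasp-1 peak also lay in the promoter window of K01G5.10, and the rpl-15 peak in that of K11H12.8.

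Of the 25, 7 were on X and 6 of these lay outside promoters. The nearest genes to these 6 were W02H3.3 (signal 789.8), cest-16 (738.7), K02D3.1 (664.0), Y41G9A.17 (627.0), F20B6.9 (625.9) and F55G7.5 (607.8), with 5′ ends between 1392 and 6045 bp from the summit. The nearest gene to a distal summit need not be its target. Among the 25, 4 lay within 200 bp of a small noncoding RNA gene, namely those nearest to pxn-1 (753.2), ins-13 (728.6), egg-5 and F55C5.17 (580.0). The remaining distal peaks of the 25 lay in introns, with ints-8 (600.6) and ppfr-1 (577.6) as the nearest 5′ ends.

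Peaks were more frequent in promoters than at random positions and less frequent in gene bodies. Of 945 summits, 437 (46.2%) lay in a promoter window, against 21.2% ± 1.30 (SD over 1000 placements) at random, a 2.18-fold excess. Exons held 83 summits (8.78%, 0.380-fold of random) and introns 200 (21.2%, 0.688-fold). These 3 differences had an adjusted permutation p of 0.00266 over 4 classes (two-sided raw p 0.002, the smallest that the placements can give). Each summit falls in only 1 class, so the promoter excess by itself lowers the shares of the other classes. The exon and intron differences are therefore not separate from it. Depletion of exons or introns among summits outside promoters was not tested. Intergenic sequence held 225 summits (23.8%, against 25% at random, adjusted permutation p = 0.466). Without the peaks near tRNA, snRNA and snoRNA genes the intergenic share was 0.830-fold of random (adjusted permutation p = 0.00999). Promoter peaks also had a higher median signal than the other 508 peaks, 193.7 against 176.4 (two-sided permutation p = 0.00022, adjusted p = 0.00044 over 2 comparisons). Among the 472 peaks of highest signal that difference, then 19.2, did not pass the test (adjusted permutation p = 0.140).

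Chromosome III carried more peaks than its length would give and chromosome V fewer. There were 158 peaks on III (1.22-fold, exact binomial adjusted p = 0.0218 over 7 tests) and 143 on V (0.725-fold, adjusted p = 5.9e-05). The central 50% of autosome length held 416 peaks (55.2% of the autosomal peaks, 1.10-fold, adjusted exact p = 0.0175). X, which carries spr-3 itself, held 191 peaks (1.14-fold) and IV 141 (0.855-fold), neither past the threshold (adjusted exact p = 0.0629 for both), and I and II held 149 (adjusted p = 0.524) and 163 (adjusted p = 0.0998). Of the X peaks, 82 lay near tRNA, snRNA or snoRNA genes, and the other 109 were 0.910-fold of the share of X (adjusted exact p = 0.291). The calls on III and on the central part were lost without replicate 2 (adjusted exact p = 0.0721 for both), that on the central part also among the 472 peaks of highest signal (adjusted p = 0.325) and without the peaks near small RNA genes (adjusted p = 0.0840), and X passed without replicate 1 (1.16-fold, adjusted p = 0.0415). Peaks on X did not differ detectably in signal from autosomal peaks (medians 186.5 and 182.4, permutation p = 0.560).

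Small noncoding RNA genes were the most over-represented class of site. Summits within 200 bp of a tRNA gene numbered 174, 61.2-fold above the 2.84 ± 1.77 found at random positions, and 198 of the 612 tRNA genes (32.4%, 28.7 to 36.2%) had such a peak. The highest lay between a pair of tRNA-Ala genes, F15G9.t1 and F15G9.t2, on X (9743593 to 9743735, signal 424.7). Genes for snoRNAs, which guide modification of ribosomal RNA, had 73 peaks (42.1-fold, 72 of 346 genes), with the highest at ZK994.7 (753.2) and C51F7.4 (580.0). Genes for snRNAs had 21 peaks (37.7-fold, 15 of 129 genes), and the strongest of them stood at sls-2.2 (728.6) and sls-2.4 (718.3), which encode spliced-leader RNAs used in trans-splicing.

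Peaks lay near 5 of 261 miRNA genes (6 peaks, 5.06-fold, adjusted permutation p = 0.00719), including mir-51 (208.2) and mir-52 (203.3). Genes for piRNAs were depleted, with 7 peaks at 6 of 15363 genes (0.257-fold), among them 21ur-13751 (541.3) and 21ur-12279 (316.0). The 20 rRNA genes had none, which at that number allows a share of up to 16.8% (exact interval). For tRNA, snRNA, snoRNA and piRNA the adjusted permutation p was 0.003 over 6 classes (two-sided raw p 0.002, the smallest that the placements can give). Drawing the random summits from other pooled candidates lowered the excess to 16.8-fold for tRNA, 14.9-fold for snRNA and 19.6-fold for snoRNA genes, all with an adjusted permutation p of 0.004, and ended the calls for miRNA (2.81-fold, adjusted p = 0.111) and piRNA genes (1.05-fold, adjusted p = 1). The miRNA call was also lost without replicate 1 (3.36-fold, adjusted permutation p = 0.0767).

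**Figure D2:**
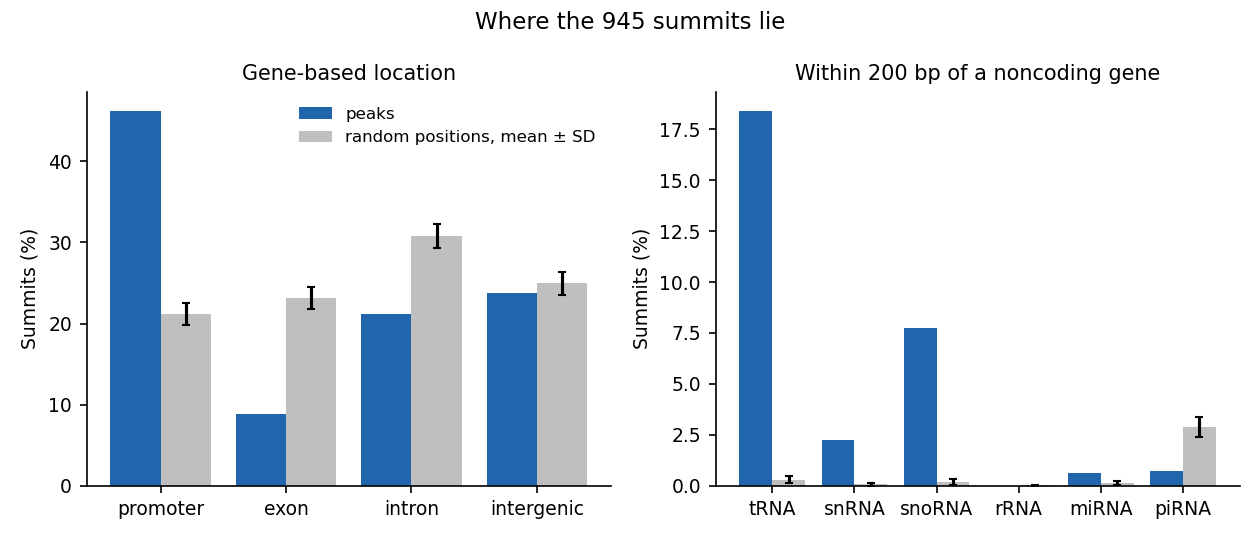
Percent of the 945 summits (y axes, blue bars) in each gene-based class (left) and within 200 bp of each class of noncoding gene (right), with the mean and SD of 1000 random placements in grey. Promoters hold 46.2% of summits against 21.2% at random, and tRNA genes 18.4%.

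Among gene lists, those of ribosomal protein, translation, respiratory chain, heat shock and stress, and DREAM and synMuv B genes had promoter peaks more often than other genes. Of all 19973 protein-coding genes, 566 (2.83%) had one. Ribosomal protein genes had the smallest p, with a peak at 27 of 83 (32.5%, 22.6 to 43.7%; odds ratio 17.3, Fisher exact adjusted p = 2.0e-20 over 19 lists). Their highest peaks were those of rpl-3 (1220), rpl-20 (1002), rpl-15 (846.0) and rpl-12 (575.3). The 27 genes shared 25 distinct peaks, and 17 of these also lay in the promoter window of another gene.

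DREAM and synMuv B genes, which include transcriptional repressors of cell cycle and germline genes, had a peak at 5 of 15 (33.3%, odds ratio 17.3, adjusted exact p = 4.0e-04). The highest 4 were lin-54 (575.3), lin-53 (440.8), lin-9 (353.6) and efl-1 (200.3), the last 2 of which encode a DREAM subunit and an E2F-like factor. The lin-54 peak was the same peak as that of rpl-12, and 4 of the 5 were shared with a neighbouring gene. Translation factor and tRNA synthetase genes had 9 of 70 (12.9%, odds ratio 5.12, adjusted exact p = 9.8e-04), led by iff-2 (402.2), eif-3.C (297.4), ears-2 (263.7) and eef-2 (217.2). Respiratory chain genes had 7 of 47 (14.9%, odds ratio 6.06, adjusted exact p = 0.00158), led by cox-5A (805.2), the ATP synthase gene atp-1 (316.0), cox-5B (244.6) and the succinate dehydrogenase gene mev-1 (240.1). Heat shock and stress genes had 8 of 79 (10.1%, odds ratio 3.90, adjusted exact p = 0.00671), led by hsp-60 (658.1), hsp-3 (285.5), hsp-1 (264.1) and the glutathione S-transferase gene gst-27 (258.7). The gst-27 peak also lay within 200 bp of a snoRNA gene.

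When each peak was given only to the gene with the nearest 5′ end, at any distance, the ribosomal protein list alone stayed past the threshold (odds ratio 5.45, adjusted exact p = 6.9e-06). The others then had odds ratios of 5.63 for DREAM and synMuv B (adjusted exact p = 0.0908), 2.92 for translation (adjusted p = 0.0610), 2.68 for respiration (adjusted p = 0.154) and 2.19 for heat shock genes (adjusted p = 0.225), and the heat shock call was also lost without replicate 2 (2.54, adjusted p = 0.211) and without operon-like genes (3.27, adjusted p = 0.0907).

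The neuronal, tissue-specific and other lists did not pass the test. Pan-neuronal genes (0 of 30, Fisher exact adjusted p = 1), neurotransmitter genes (0 of 20, adjusted p = 1), muscle genes (0 of 38, adjusted p = 0.918) and intestine genes (0 of 32, adjusted p = 1) had no promoter peak. Nuclear hormone receptor genes had 3 of 274 (nhr-47, 344.5; nhr-142, 222.9; nhr-114, 140.3; adjusted exact p = 0.26), neuropeptide genes 2 of 140 (ins-39, 349.1; nlp-76, 167.2; adjusted p = 0.834) and cuticle collagen genes 1 of 175 (col-185, 210.0; adjusted p = 0.212). Homeobox genes had 1 of 93 (ceh-38, 144.8; adjusted exact p = 0.834), germline genes 1 of 59 (mex-1, 162.5; adjusted p = 1) and sperm genes 1 of 85 (spe-48, 289.0; adjusted p = 0.999). Histone genes had 2 of 81 (his-37, 333.2; htz-1, 139.4; adjusted exact p = 1) and cell cycle genes 2 of 40 (pcn-1, 382.3; lin-23, 154.3; adjusted p = 0.663). The CoREST, demethylase and deacetylase list, which includes the CoREST gene spr-1 and the demethylase gene spr-5, had 1 of 26 (rbr-2, 164.1, adjusted exact p = 0.834). As this list also holds histone methyltransferase genes and genes of their complexes, its count is not one of its named kinds alone. In such short lists the upper bound of the share is wide, reaching 11.6% for pan-neuronal genes and 16.8% for neurotransmitter genes. The col-185 peak lay 890 bp upstream of that gene and within 200 bp of a tRNA gene.

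**Figure D3:**
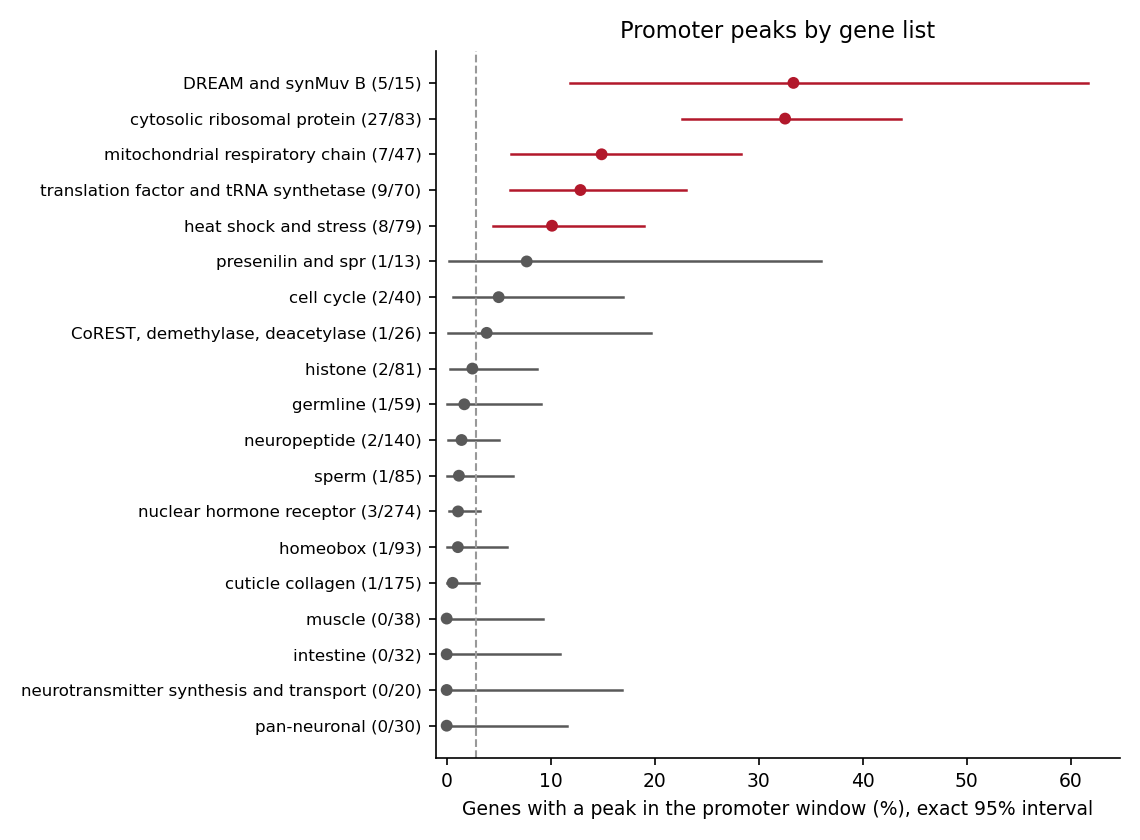
Percent of the genes of each list with a peak in the promoter window (x axis; points, with exact 95% intervals as lines; counts beside the names), in red where the adjusted p is under 0.05, and the share of all protein-coding genes, 2.83%, as a dashed line. The DREAM and synMuv B (33.3%) and ribosomal protein (32.5%) lists stand farthest to the right.

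Because spr-3 was found through presenilin, the presenilin pathway and the other spr genes were examined one by one. Of the 13 genes, only spr-2, which encodes a nucleosome assembly protein-like factor, had a thresholded promoter peak (IV 8891186 to 8891615, 61 bp upstream, signal 160.7, rank 649; list adjusted exact p = 0.663). No pooled candidate lay in the promoter windows of 8 genes, namely the presenilin genes sel-12 and hop-1, the gamma-secretase genes aph-1, aph-2 and pen-2, the Notch receptor genes lin-12 and glp-1, and spr-5. The windows of glp-1, lin-12, pen-2 and sel-12 also held no candidate in either replicate. Weaker candidates stood at sel-10 (130.9, rank 1085), spr-4 (87.4, rank 4395), spr-1 (60.7, rank 14434) and spr-3 itself (58.3, rank 16124). Of all protein-coding genes, 32.7% had a pooled candidate of any rank in the window.

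The transgene carries extra copies of spr-3 and unc-119, so both loci were examined. Peaks clustered around spr-3 (X 4514093 to 4516895): 7 lay within 25 kb, against 0.53 ± 0.875 in random windows (one-sided permutation p = 0.001, the smallest that the 1000 windows can give). Their strongest was at the promoter of pdi-2, a protein disulfide isomerase gene (X 4524093 to 4524215, signal 370.7, rank 82). In the same window replicate 1 had 30 candidates (15.3 ± 6.64 at random, permutation p = 0.024) and replicate 2 had 39 (15.4 ± 6.92, p = 0.003). Around unc-119 there were 0 peaks, and 9 and 13 candidates in replicates 1 and 2 (permutation p = 0.836 and 0.635), with a weak candidate at its promoter (45.5, rank 27585).

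**Figure D4:**
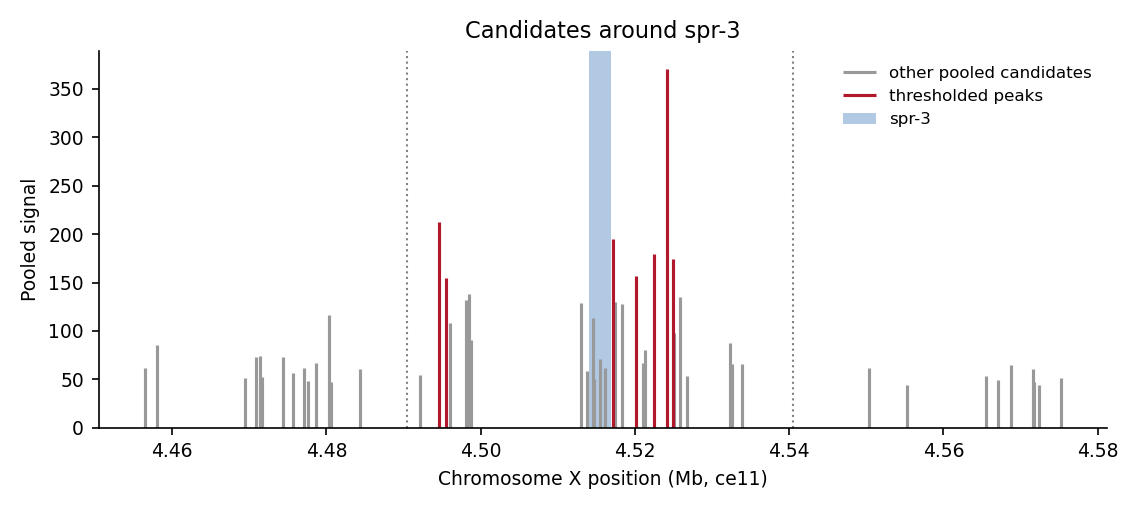
Pooled signal (y axis) of the candidates around spr-3 by position on chromosome X (x axis, Mb, ce11), thresholded peaks in red, other candidates in grey, the gene as a blue band, and dotted lines 25 kb on each side of its middle. The 7 thresholded peaks lie on both sides of the gene, and the strongest, at pdi-2, has a signal of 370.7.

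Short sequences with the core GACGC and, at promoters, with the core GCGCCAGC, were more frequent at summits than beside them. Of 32656 8-mers tested, 808 passed the threshold. The leading word was GAGACGCA, found in 75 of 945 summit windows (7.94%) and 0.530% of 1888 flank windows (15-fold, one-sided Fisher exact adjusted p = 5.6e-22), and the overlapping words AGACGCAG (77 windows), GACGCAGA (67) and AGAGACGC (55) followed closely. Words that match the internal promoter boxes of tRNA genes were also among the highest: 49 of the 50 windows with CTGAGCTA and 46 of the 57 with GGGTTCGA lay near tRNA genes. GCGCCAGC was present in 42 windows, 38 of them in promoters and 0 near tRNA genes (42-fold, adjusted exact p = 1.0e-14).

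Of 12 leading words tested for position, 4 lay closer to the summit than chance. GCGCCAGC lay within 25 bp of it in 55.3% of occurrences, AAACGCGC in 53.5%, CGCCAGCA in 52.5% and GCGTCAGC in 61.3%, against 34.7% expected (one-sided exact binomial adjusted p = 0.0182, 0.0354, 0.0472 and 0.0182). GAGACGCA did so in 41.7% (adjusted exact p = 0.205). Overlapping words were then grouped after they had been seen. The GAGACGCA group was present at 12.8% of promoter peaks and 13.9% of other peaks away from small RNA genes, the GCGCCAGC group at 13.3% and 1.29%, and the AGAGAGAG group at 11.7% and 16.8%. At peaks near tRNA, snRNA and snoRNA genes the groups were present at 3.00%, 1.87% and 6.37%. With those peaks left out, 315 words passed, and GAGACGCA still led (15.8-fold). Other settings had other leading words: GGGTTCGA against promoters without a peak, CTGAGCTA at peaks outside promoters and AGACGCAG without replicate 2.

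**Figure D5:**
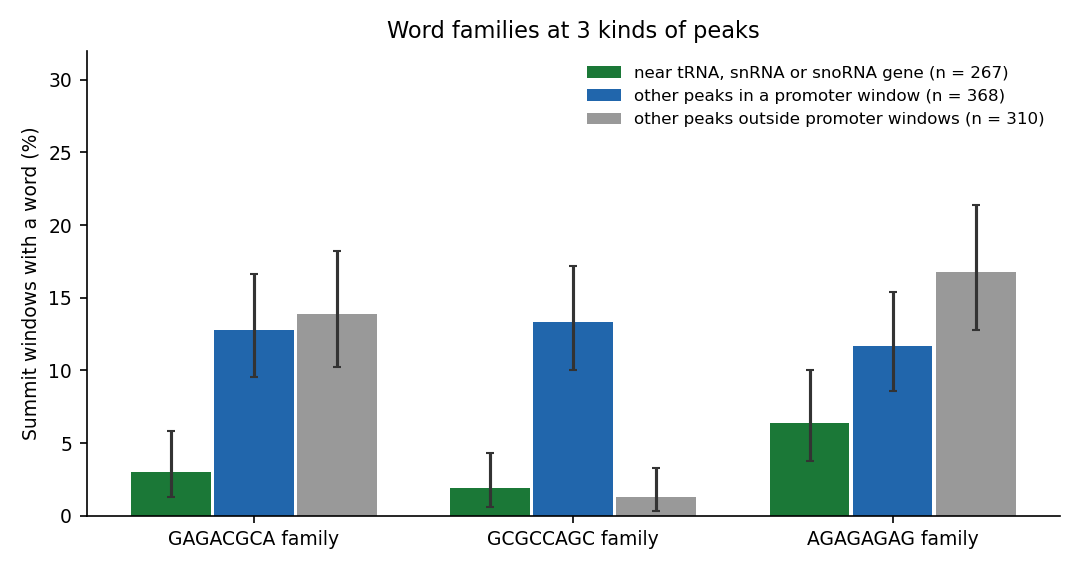
Percent of summit windows holding a word of each of 3 groups of overlapping words (y axis, bars with exact 95% intervals), for peaks near tRNA, snRNA or snoRNA genes (green, n = 267), other promoter peaks (blue, n = 368) and other peaks outside promoters (grey, n = 310). The GCGCCAGC group stands at 13.3% of the promoter peaks and 1.29% of the other distal peaks.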

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

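In this part the following tests were chosen only after the result was seen: all tests on the lower-ranked candidates, the setting without peaks near small RNA genes (though its outcome for ribosomal protein genes was not yet known), the comparison of once-only with copied tRNA genes, that of abundantly transcribed tissue genes, and both tests at spr-3. The design has 1 group and gives no biological contrast, so no biological explanation was tested for the tRNA and ribosomal protein patterns, and only binding at its own promoter for spr-3.

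Candidates outside the thresholded set also lay at small RNA genes. Among the 945 pooled candidates ranked 946 to 1890, 75 lay within 200 bp of a tRNA gene (2.73 ± 1.66 at random positions, highest 11), 7 of a snRNA gene (0.57 ± 0.747) and 13 of a snoRNA gene (1.74 ± 1.29), each with an adjusted permutation p of 0.003 over 6 classes (two-sided raw p 0.002, the smallest that the placements can give).

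In the same ranks 6 of 30 pan-neuronal genes had a candidate in the promoter window (odds ratio 14.5, Fisher exact adjusted p = 2.0e-04 over 19 lists), namely egl-3, syd-2, ida-1, unc-33, rgef-1 and unc-76, while none had a thresholded peak. The single replicates gave 3 of 30 genes each at these ranks (adjusted exact p = 0.126 and 0.120), the pooled ranks 1 to 1890 gave an adjusted p of 0.00584, and ranks 1891 to 2835 gave 1 of 30. Over ranks 1 to 1890 neither replicate passed (3 and 4 of 30, adjusted exact p = 0.203 and 0.115), and over ranks 1891 to 2835 they gave 1 and 3 of 30. Histone genes had 6 of 81 (odds ratio 4.61, adjusted exact p = 0.0264), from only 3 candidates, each in the windows of a pair of genes such as his-61 and his-62, and the single replicates gave 4 of 81 each (adjusted p = 0.126 and 0.207). The histone call was lost over ranks 1 to 1890 (odds ratio 2.03, adjusted exact p = 0.237), and ranks 1891 to 2835 gave 0 of 81.

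Peaks at tRNA genes were weighed against reads shared between identical gene copies. Of the 140 tRNA genes whose sequence occurs once in the genome, 19.3% had a peak (exact 95% interval 13.1 to 26.8%), against 0.465% at random positions (highest 1.63%). The share was higher among the 472 genes with identical copies, 36.2%, with an odds ratio of 0.421 for once-only genes (two-sided Fisher exact p = 1.3e-04). Shared reads may account for part of the difference, but how reads that match several copies were placed is not given in the sources used here. Other differences between copied and once-only genes were not tested. With 19.3% of once-only genes at a peak, a peak within 200 bp did not require an identical copy of the gene itself. Once-only genes near a copied tRNA gene, or differing from another by few bases, were not set apart. Shared reads as the whole cause therefore stay open. Whether tRNA genes are pulled down whatever the tagged protein was not tested, as no untagged worms were analysed here.

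Peaks at ribosomal protein promoters were weighed against small RNA genes lying beside them. With peaks within 200 bp of tRNA, snRNA and snoRNA genes left out, 26 of the 83 genes had a peak in place of 27. The odds ratio of the list was then 19.1 (95% interval 11.9 to 30.7). Its rise from 17.3 came with fewer other genes with a peak, 463 in place of 539. These values argue against small RNA genes within 200 bp of the summit as the cause. Small RNA genes farther off were not tested. Pull-down of highly transcribed promoters whatever the tagged protein cannot be told apart from binding: only 0.671% of 298 muscle, sperm and cuticle collagen genes had a peak (exact 95% interval 0.0814 to 2.40%), but these are transcribed in single tissues, and neither transcript levels nor untagged worms were analysed here.

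The peaks around spr-3 were weighed against extra copies of the transgene. With the gene and 1 kb on each side left out, 11 pooled candidates within 25 kb were among the highest 5% of all candidates, 6 of them thresholded peaks that make up the pattern, while 0 of 14 candidates between 25 and 50 kb away were. The other 5 exceeded the 0.253 ± 0.576 of random windows (95th percentile 1, one-sided permutation p = 0.003) and the highest count, 2, in windows with at least 6 thresholded peaks elsewhere. Such windows came from only 3 regions, too few to tell extra copies of the transgene from a cluster of sites. Extra copies therefore stay open. The 0 peaks around unc-119, which is on the same transgene, cannot decide this. How much of the window around unc-119 the transgene holds is not given in the sources used here. Binding at the promoter of spr-3 also stays open: the candidate in the promoter window ranked 25 of 28 within 25 kb, but another, 1086 bp upstream of the 5′ end and just outside that window, ranked 12.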

How the results depend on the processing

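The alternatives that left out small RNA or spr-3 peaks, drew random summits from candidates, or matched nearest summits were chosen after seeing the data. The highest candidates of the pool are the thresholded set itself, so their 43 values are left out here. Of the other 403 alternative values over 114 results, 357 kept their direction and side of the threshold or moved little, 18 reversed, 17 were weaker, 3 stronger and 8 moved; the cause was not tested except where the construction shows it. No paired analysis was possible because the series has only 1 group. With the 472 peaks of highest signal the central autosome excess was 1.05-fold, the promoter difference in signal 19.2, the X difference in signal -0.144, the number of enriched words 286, and the odds ratios of the presenilin and CoREST lists 0. With small RNA peaks left out, 678 peaks were tested. Intergenic peaks were then 0.830-fold, X 0.910-fold, the central part 1.09-fold, the histone list 1.01 and the words 315. Words numbered 2659 against 19395 promoters without a peak, a background of another kind and size, and 232 at the 508 distal peaks. A distance of 500 bp lowered the excess to 30.3-fold for tRNA, 18.8-fold for snRNA and 22.6-fold for snoRNA genes. Random draws from candidates gave 2.81-fold for miRNA and 1.05-fold for piRNA genes. A 500 bp promoter window gave 1.06-fold for intergenic peaks, and odds ratios of 0 for CoREST and 1.09 for histone genes. Nearest-gene assignment left 1 list past the threshold in place of 5, with odds ratios of 5.63 (DREAM and synMuv B), 2.92 (translation), 2.68 (respiration), 2.19 (heat shock), 2.50 (neurotransmitter) and 1.97 (collagen). Without operon-like genes the heat shock list had 3.27 and the presenilin list 0. Leaving out either replicate gave ranges of 1.19 to 1.24 for III, 1.15 to 1.16 for X, 1.08 to 1.11 for the central part, 3.36 to 5.04 for miRNA genes, 0.138 to 0.240 for piRNA genes, 8 to 11 peaks near spr-3 in place of 7, and for the lists 2.54 to 3.57 (heat shock), 0 to 1.46 (CoREST), 0 to 1.26 (pan-neuronal), 0 to 1.01 (muscle), 0 to 1.17 (intestine), 0.921 to 1.44 (histone) and 0.933 to 1.97 (cell cycle). The named peaks at rbr-2, nlp-76, ceh-38, nhr-114, mex-1, htz-1 and lin-23 fell outside the 945 highest candidates of at least 1 replicate. Promoter, exon, intron, tRNA, snRNA, snoRNA and ribosomal protein results and the spr-3 count kept their direction and side of the threshold in every alternative run, with promoter excesses of 2.05 to 2.54-fold. Library depth is unknown, so its effect on the number of peaks could not be assessed.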

Other observations

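In this part the gene families, tRNA isotypes and other gene classes were chosen only after the main results were seen, and the X word test was fixed before that word was counted but after the strong X peaks and the overall word lists had been seen.

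Genes that share a name prefix were taken as families, and 175 families of at least 10 genes were tested. Besides rps (12 of 31 genes) and rpl (14 of 47), 4 families had promoter peaks more often than other genes by two-sided Fisher exact test. These were sec genes of protein secretion (5 of 19, odds ratio 12.3, adjusted exact p = 0.00876), with sec-61.G (signal 428.6), sec-61.B (346.5), sec-15 (312.9), sec-3 (171.1) and sec-24.1 (156.6), hsp genes (5 of 22, odds ratio 10.2, adjusted p = 0.0116), lin genes (7 of 47, odds ratio 6.06, adjusted p = 0.0116) and dnj genes, which encode DnaJ-type co-chaperones (5 of 29, odds ratio 7.2, adjusted p = 0.0354), with dnj-13 (438.2) and dnj-9 (380.4) highest. The hsp and lin results overlap with those of the gene lists, since all 5 hsp genes are in the heat shock list and 4 of the 7 lin genes in the DREAM and synMuv B list, whose calls were lost under nearest-gene assignment. The rab genes of vesicle traffic had 4 of 20 (rab-11.1, rab-5, rab-7 and rab-14, adjusted exact p = 0.0538). With small RNA peaks left out they passed (odds ratio 10, adjusted exact p = 0.0315). Their count was still 4 of 20, and only the number of other genes with a peak fell, from 562 to 485. The sec-15 peak lay within 200 bp of a tRNA gene, and in that setting the sec genes had 4 of 19 (odds ratio 10.7, adjusted exact p = 0.03). Some of the peaks of these families are shared with genes of other kinds. The dnj-19 peak is also that of nhr-47, 18 bp from nhr-47 and 378 bp from dnj-19. The rab-11.1 peak is also that of the ribosomal protein gene rpl-7, and the rab-7 peak that of mex-1. Nearest-gene values are not given here for the families. The str chemoreceptor genes had 0 of 193 (adjusted exact p = 0.140).

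Peaks lay at 93 of 276 tRNA genes on X (33.7%) and at 105 of 336 on autosomes (31.2%), a difference that did not pass the test (two-sided Fisher exact p = 0.544). Of 20 tRNA isotypes, 0 differed from the rest after adjustment and 2 had an unadjusted exact p under 0.05 (tRNA-Cys, 9 of 13 genes, adjusted p = 0.131; tRNA-Phe, 1 of 14, adjusted p = 0.442). Of 4 other gene classes, ncRNA genes had 256 peaks within 200 bp (7.59-fold of random) and pseudogenes 12 (0.343-fold). Each of these had an adjusted permutation p of 0.004. The lincRNA genes had 7 (2.3-fold, adjusted permutation p = 0.0879) and antisense RNA genes 3 (2.37-fold, adjusted p = 0.272). Of the 256 ncRNA peaks, 47 lay outside promoters and away from tRNA, snRNA and snoRNA genes. They were 15.2% of all peaks of that kind, whose random share is not given here.

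The strong distal peaks on X were tested for a word. Of the 20 strongest peaks outside promoters and away from tRNA, snRNA and snoRNA genes, 12 lay on X. The hypothesis was that they coincide with sites that recruit the dosage compensation complex to X, whose known motif has the core GCGCAGGG. That word lay in 11 of the 63 X peaks of this kind (17.5%, exact 95% interval 9.05 to 29.1%) and in 0 of 247 autosomal ones (two-sided Fisher exact p = 1.2e-08). Along the genome it was 81 times on X (4.57 per Mb) and 233 times on autosomes (2.82 per Mb). Of the 11 X peaks of this kind with a signal of at least 500, 7 held it. Among these were those nearest to W02H3.3 (789.8), cest-16 (738.7), Y41G9A.17 (627.0) and F20B6.9 (625.9). Another had its nearest 5′ end at xol-1 (511.6), named here after its value was seen. The limit of 500 was not among the settings fixed beforehand. The next X peak below it, nearest to F22H10.2 (489.0), lacked the word. The other X peaks of this kind with the word had signals of 217.4 or lower. In a search of all words the reverse complement CCCTGCGC led the contrast of X with autosomal distal peaks (adjusted exact p = 2.4e-04). This is the same count over the same peaks, so it adds only the adjustment over words. Recruitment sites may thus underlie part of the distal X peaks. Whether SPR-3 binds there or these sites are pulled down whatever the tagged protein was not tested.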
